A study of Drosophila melanogaster with 18 samples.

How the data were processed

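Gene expression was measured by RNA sequencing of whole Drosophila melanogaster in 18 samples, 3 for each of 6 groups: w1118 controls and Nxt1 DG05102 over Z2-0488 trans-heterozygotes, each as wandering larvae, stationary larvae and white prepupae. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the ScriptSeq kit and sequenced as paired ends on an Illumina HiSeq. Bowtie 1.1.1, Cufflinks and Cuffdiff are the tools named, per the submitters' processing notes, which give no versions for Cufflinks and Cuffdiff and no settings. The genome build and annotation are not given in the sources used here, and coordinates are printed as in the deposited tables, counted from 1.

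The authors deposited 18 tables, 6 per stage, of tests between the genotypes at the level of genes, isoforms, transcription start-site groups, splicing within a start-site group, promoter usage and coding-sequence usage. The FPKM values (fragments per kilobase of transcript, scaled to the sequenced fragments) are 1 per genotype and stage, pooled by the authors over the replicates, and the unit is that of Cuffdiff's value columns per the file headers. The log2 fold change of the trans-heterozygotes over w1118 is a deposited column, and it was recomputed from the deposited FPKM as a check. The p-value and the q-value are deposited columns, the q-value being the authors' adjustment within a table. The test statistic, a score of opposite sign to the log2 fold change, is deposited per the file headers. The usage tables hold the square root of the Jensen-Shannon divergence, a deposited score that is 0 for identical usage. The tables hold no values per replicate and no counts, so the depth of each sample is unknown, and edgeR or limma fits, fits with a replicate block, fits without 1 replicate and other splits of the samples were not possible. The scaling of each stage's tables was done by the authors within that stage, per the file headers, so levels of different stages are not on 1 scale.

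A gene was called when its deposited status was OK and its deposited q was at most 0.05. The fold change is the ratio of the deposited FPKM, and no fold is printed where a genotype is listed at 0. The standard error of a log2 fold change was taken as its size divided by that of the deposited test statistic, after a check that the deposited p-value followed from the statistic's normal tail for nearly all tested genes. The difference of the genotype effect between stages was tested per gene with a two-sided normal test, adjusted with the Benjamini-Hochberg method over the genes tested at both stages. The stages have separate controls. Gene lists were compared with the other tested genes by one-sided Fisher's exact tests per direction, adjusted over 156 tests. For each list the median of log2((FPKM + 1) ratios) was placed among 10000 random lists matched on mean FPKM in 20 bins, as a description of these pooled values. Benjamini-Hochberg adjustment of the deposited p over the list alone was also made. Locus spans, taken from the deposited coordinates, were put into 5 equal bins, and the longest was compared with the shortest by Fisher's exact test. Chromosome arms were compared in the same way. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used.

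The 26 gene lists cover mRNA export, exon junction and splicing factors, muscle structural and sarcomere genes, muscle attachment, neuronal genes, haemocytes, fat body and larval serum, salivary glue, early ecdysone response, the 71E cluster, ecdysone synthesis, insulin, TOR and juvenile hormone signalling, immune-induced genes, heat shock and chaperones, detoxification, cell death and stress, testis transcripts, male dosage compensation, glycolysis, the proteasome regulatory particle, ribosomal proteins, histones, the respiratory chain and ATP synthase, cuticle, digestive enzymes, and the construct markers w and y. The lists matched 781 entries of the deposited tables, and 9 listed symbols matched none. Of 14542 gene entries, 448 hold several symbols and 5896 share a locus with another entry. Reads of near-identical copies, such as the Hsp70, Amy and Att genes, and of overlapping genes cannot be told apart in the deposited values, since the counting is not described. In the splicing table of stationary larvae, 6 symbols had been turned into dates, and symbols were taken from the entry identifiers instead.

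Genes were named by a rule: at each stage Nxt1, sbr, abba, w, y, roX1 and roX2, then the 10 largest rises and 10 largest falls in log2((FPKM + 1) ratio) among called genes with a larger FPKM of at least 5 and an informative symbol. The 3 largest of each direction among genes with a CG or CR number were added. From each list up to 4 called members with the largest change and up to 2 uncalled members with the highest mean FPKM were eligible. Across stages the 10 genes of each direction with the largest smallest change, and the 5 with the smallest p for the difference between wandering larvae and prepupae, were named. For usage, the 5 called genes with the largest distance at each stage and those called at all 3 stages, at most 10, were eligible. Rbp4, bam, MtnD and MtnE were looked up outside this rule, and of these only Rbp4 is printed. CR40596 in stationary larvae and the regulators aly, comr, topi and tomb were also looked up outside it.

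The steps were tested on simulated data. For the difference between wandering and stationary larvae, simulated over 10459 genes with 200 changed, the test recovered 8% of changes of 1 and 79% of changes of 3 on the log2 scale, with 4 false calls. For stationary larvae and prepupae, over 10338 genes, it recovered 15% and 84%, also with 4 false calls. The simulated errors were drawn with the same standard errors that the test used. The false calls therefore do not check whether those standard errors match the spread between replicates. Of 40 unchanged simulated lists of 30 members drawn from the 11128 genes of stationary larvae, 2 fell outside the central 95% of random lists. The same lists were then shifted by a constant well beyond that range, so that 40 of 40 lay above it was nearly fixed beforehand. The check does not cover lists of few members, whose range is wider. For the 7 tested glue genes it was -0.54 to 0.51 in stationary larvae. For locus span in stationary larvae, a true odds ratio of 2 was recovered with a median of 1.97 over 200 simulations of 11128 genes.

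The alternatives tried were a q of at most 0.01, a minimum 2-fold change, a larger FPKM of at least 1, a Benjamini-Hochberg adjustment recomputed within each table, centring of log2 ratios on the median, calls from start-site groups, pseudocounts of 0.1 and 5 FPKM, span bins matched on FPKM, and leaving out entries that share a locus. Intron lengths were not analysed here, because no annotation is named as the one behind the tables.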

Results

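Whole animals of Drosophila melanogaster were profiled by RNA sequencing in 2 genotypes at 3 stages around the onset of metamorphosis. The control genotype was w1118, a white-eyed laboratory strain, and the other genotype carried 2 alleles of Nxt1, DG05102 and Z2-0488, in trans. Nxt1 is the small partner of the mRNA export receptor sbr, the fly NXF1, and together they carry messenger RNA out of the nucleus. The stages were wandering larvae, stationary larvae and white prepupae, with 3 samples per genotype and stage, 18 in all. The stages were told apart with the help of food dyed with 0.05% bromophenol blue. For each stage the authors' deposited tables held 1 pooled FPKM (fragments per kilobase of transcript, scaled to the sequenced fragments) per genotype, so no spread between the replicates can be given. The depth of each sample is unknown, because the tables hold no counts. Errors printed after a log2 fold change are standard errors derived from the authors' test statistics, and q is the authors' adjusted p-value. The labels give the control strain as w1118 and the trans-heterozygotes as yw, so every difference below is one of genotype and strain background together. Every FPKM, log2 fold change and q of a gene is the value of the authors' deposited table for that stage.

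The first question was whether the targeted gene and its partners differed at the transcript level. Nxt1 (arm 2R, 19696768 to 19699496, build not given in the sources used here) had 11.6 and 9.28 FPKM in w1118 and trans-heterozygous wandering larvae. The corresponding values were 11.5 and 15.5 FPKM in stationary larvae and 10.6 and 17.9 FPKM in prepupae, and Nxt1 was called at none of the 3 stages (q = 0.998, 0.788 and 0.480). Its log2 fold changes carried large standard errors, -0.33 ± 0.72, 0.43 ± 0.62 and 0.76 ± 0.58, and its locus was shared with a neighbouring gene. The lesions of the alleles are not given in the labels, so the transcript level does not check them. The export receptor sbr had 27.7 and 40.6 FPKM in wandering larvae and was not called at any stage (q = 0.399, 0.440 and 0.112). Of the 22 tested members of the mRNA export list, 1 was called lower in wandering larvae, 1 in stationary larvae and 2 in prepupae, and none was called higher (0, 1 and 2 lower adjusted over the list alone). The list's median log2 ratio was 0.05 in wandering larvae, 0.18 in stationary larvae and 0.15 in prepupae, at percentiles 73.9, 98.1 and 97.9 of expression-matched random lists. The member called at every stage, in wandering larvae only when adjusted over all genes, was nxf4, a relative of sbr, which fell 8.73-fold in wandering larvae, 13-fold in stationary larvae and 14.8-fold in prepupae from w1118 levels of 4.18, 6.21 and 4.35 FPKM. Whole animals do not show the tissue in which nxf4 fell, and whether its fall is part of the loss of testis transcripts described below was not tested. The entry that merges xmas-2, part of the complex that couples transcription to export, with xmas-1 fell from 14.2 to 8.56 FPKM in prepupae (q = 0.0189). The authors' usage tests called this entry in stationary larvae for promoters (q = 0.00894) and coding sequences (q = 0.0132). Its fall therefore cannot be assigned to xmas-2. The abundant adaptor Ref1 and helicase Hel25E were not called, at 129 and 99.7 FPKM and 88.8 and 93.5 FPKM in stationary larvae. Among 22 tested exon junction and splicing factors none was called in either larval stage, and in prepupae Srp54 and tsu fell from 73.1 to 46.0 FPKM and from 263 to 184 FPKM.

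In wandering larvae, transcripts of the male germline fell in the trans-heterozygotes, several of them by more than 10-fold, while muscle, digestive and detoxification transcripts were among those that rose. S-Lap7, S-Lap3 and S-Lap1, leucyl aminopeptidases of sperm, fell from 68.0 to 1.09 FPKM, from 129 to 4.39 FPKM and from 138 to 7.09 FPKM. w-cup, of the cup genes transcribed late in spermatogenesis, fell 47.1-fold, from 66.0 to 1.40 FPKM, and Tpl94D, a transition protein of sperm chromatin, fell from 31.0 to 0.251 FPKM. On the other side, the myosin heavy chain Mhc rose 3.29-fold and the amylase Amy-d rose 8.31-fold. Of 10898 tested genes, the authors' deposited table called 1284, of which 1034 were lower and 250 higher in the trans-heterozygotes. At least 4-fold changes were held by 705 of the lower and 59 of the higher genes.

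The testis list, fixed before the data were examined, had 34 of 56 tested members lower in wandering larvae and 0 higher (37 lower adjusted over the list alone). That was 60.7% of the list against 9.22% of the other tested genes (one-sided Fisher's exact test over genes, q = 2.17e-19). Its median log2 ratio of -2.23 lay at percentile 0 of 10000 expression-matched random lists. Further large falls were those of Acam, a testis calmodulin relative, from 47.1 to 1.37 FPKM, of the dynein light chain relative robl62A from 78.4 to 2.87 FPKM, of ran-like from 24.2 to 0.0647 FPKM, of spaw from 25.5 to 0.429 FPKM and of I-t, a testis phosphatase inhibitor, from 43.5 to 1.46 FPKM. Among genes without a name, CG12860 fell from 119.7 to 1.64 FPKM, CG31909 from 123 to 3.39 FPKM and CG43638 from 56.1 to 0.332 FPKM. The list members janA,janB (1 merged entry) and Mst84Dc were not called, with 133 and 90.5 FPKM and 71.1 and 20.8 FPKM. The male-specific dosage compensation RNA roX1 rose from 209 to 322 FPKM (log2 fold change 0.62 ± 0.22, q = 0.0449), while roX2 at 40.6 and 42.3 FPKM was not called.

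Muscle genes went both ways in wandering larvae, with 8 of 43 tested members of the sarcomere list higher and 3 lower (higher calls, q = 4.84e-05; 11 higher and 4 lower adjusted over the list alone). The troponin C TpnC47D rose from 30.7 to 109 FPKM, Mhc from 42.9 to 141 FPKM, Unc-89 from 1.27 to 4.62 FPKM and Mlp60A from 28.0 to 64.0 FPKM. abba, the fly TRIM32 homologue also called thin, which keeps larval muscle intact, fell from 48.1 to 23.5 FPKM (log2 fold change -1.03 ± 0.24, q = 2.3e-04). The thick filament gene Mf and the Z-disc gene Zasp66 were not called, at 708 and 748 FPKM and 1573 and 966 FPKM. In the muscle attachment list LanA, a laminin chain, fell from 101 to 52.1 FPKM, and the entry that merges the integrin mew with CG15742 fell from 37.6 to 19.9 FPKM. The coding-sequence usage of that entry differed between the genotypes at every stage, so its falls here and below cannot be assigned to mew. The other 13 of 15 tested members were not called. Of the 45 tested digestive enzymes 14 rose and 3 fell (higher calls, q = 1.07e-11; 18 and 4 adjusted over the list alone). Amy-p rose from 33.2 to 182 FPKM and the maltase Mal-A3 from 0.187 to 12.5 FPKM, whereas the protease Jon66Cii fell from 123 to 5.50 FPKM. Detoxification genes had 17 of 52 members higher and 6 lower (higher calls, q = 1.87e-14; 24 and 6 adjusted over the list alone). Among them the cytochrome P450 gene Cyp6a23 rose from 7.97 to 77.7 FPKM, the glutathione transferase GstD2 from 7.56 to 59.5 FPKM and Cyp28d1 from 22.7 to 87.3 FPKM, while Cyp6a17 fell from 10.3 to 0.246 FPKM.

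Other groups were smaller or mixed in wandering larvae. Of 13 tested haemocyte genes 4 rose and none fell (q = 0.00122), with the prophenoloxidases proPO-A1 and proPO45 going from 8.91 to 47.6 FPKM and from 9.10 to 43.0 FPKM, and Hml and Pxn from 9.38 to 16.2 FPKM and from 18.3 to 29.9 FPKM. Of 23 heat shock genes 5 fell and none rose (lower calls, q = 0.350), led by the near-identical copies Hsp70Bb, from 10.2 to 3.20 FPKM, and Hsp70Ba, from 3.77 to 0.906 FPKM. In the immune list 2 of 42 members rose and 3 fell, neither beyond the other genes by Fisher's test, with a median log2 ratio of 0.22 at percentile 100. The stress peptide TotA fell from 1981 to 349 FPKM and AttA from 17.4 to 4.68 FPKM, while PGRP-SC2 rose from 188 to 617 FPKM and the diptericin Dpt from 32.5 to 77.5 FPKM. Other large rises included those of the cuticle gene Cpr47Ec from 4.57 to 38.5 FPKM, Sytalpha from 0.944 to 17.6 FPKM, Nplp2 from 13.4 to 78.0 FPKM, nol from 11.4 to 64.4 FPKM, and Cpr47Eg, listed at 0 in w1118 and at 11.1 FPKM in the trans-heterozygotes. Without a name, CR40469 rose from 249 to 3633 FPKM and CG17352 from 0.540 to 25.9 FPKM. The early ecdysone list had 2 members lower and 1 higher of 25, the synthesis list 1 lower of 14, and none of 25 tested neuronal genes, 7 glue genes, 6 genes of the 71E cluster, 15 fat body genes and 15 insulin, TOR and juvenile hormone genes was called. The median log2 ratio of the uncalled neuronal list was nevertheless 0.27, at percentile 100 of the random lists, and that of the 71E cluster -1.13, at percentile 0.690. The count of higher genes was the least firm of this stage, at 165 at a q of 0.01 and 93 when called through start-site groups.

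**Figure D1:**
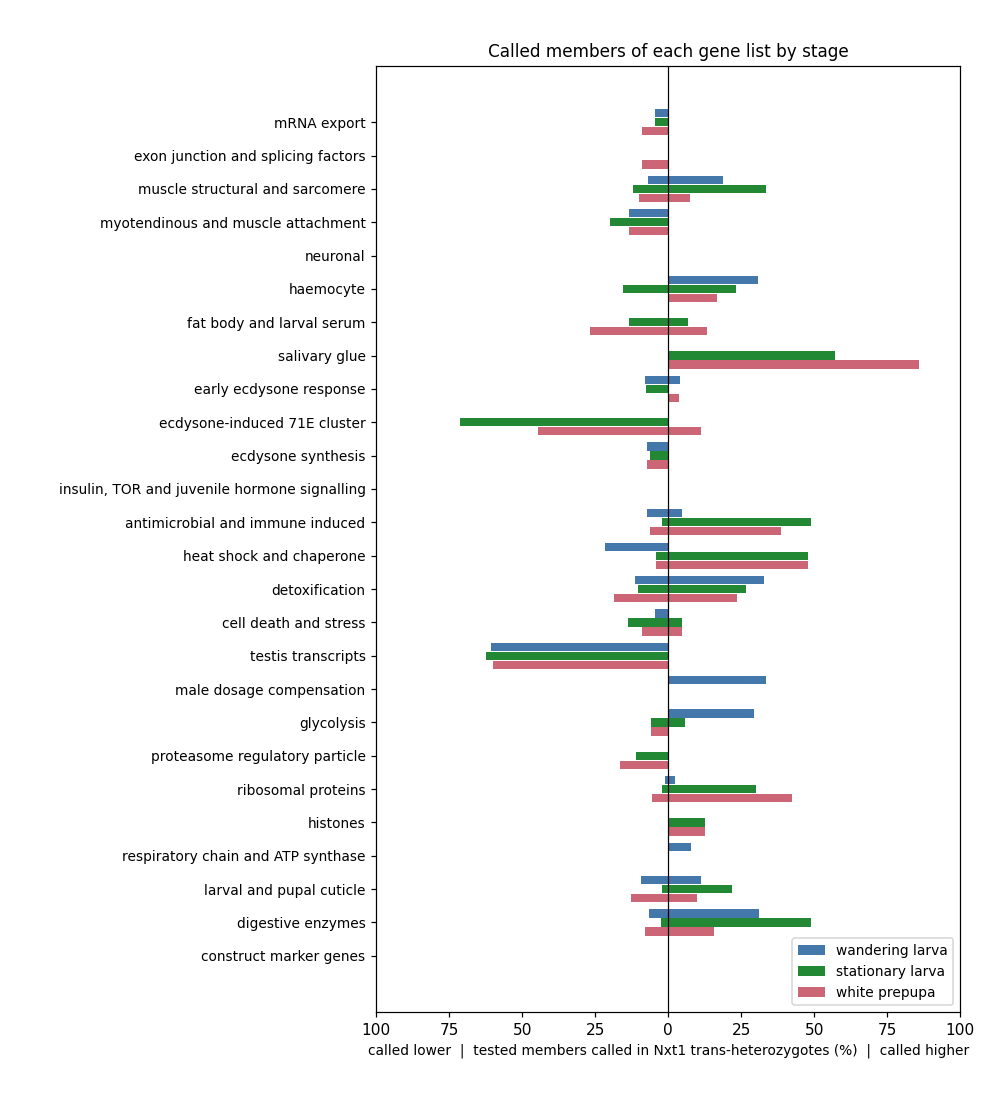
Share of the tested members of each gene list that the deposited gene test called lower (bars to the left, percent) or higher (bars to the right, percent) in Nxt1 trans-heterozygotes, with 1 bar per stage. The testis list reaches 62.5% lower in stationary larvae and has no bar to the right.

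In stationary larvae the male germline transcripts were again lower, and antimicrobial peptide, heat shock, digestive and glue transcripts and part of the muscle transcripts were higher. Dpt rose 9.65-fold, from 74.0 to 713 FPKM, and the stress peptide TotC rose from 3.91 to 129 FPKM. The Hsp70Aa entry rose 11.8-fold, from 9.23 to 109 FPKM, and Mhc rose 8.09-fold, from 5.93 to 47.9 FPKM. w-cup fell 89-fold and the don juan gene dj, which encodes a sperm tail protein, fell 30.9-fold. The authors' deposited table called 1991 of 11128 tested genes, 1468 lower and 523 higher, with 866 of the lower and 155 of the higher changed at least 4-fold. Called through start-site groups, 286 genes were higher.

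The immune list had 24 of 49 tested members higher and 1 lower (30 and 1 adjusted over the list alone), against 4.50% of other genes higher (q = 8.83e-18). Its median log2 ratio was 1.12, at percentile 100 of the random lists. The peptide edin rose 9.79-fold and Dro rose from 7.15 to 66.5 FPKM, and TotB and TotZ, outside the list, rose from 7.22 to 92.3 FPKM and from 1.39 to 21.9 FPKM. TotA and IM1 were not called, at 1731 and 1733 FPKM and 182 and 287 FPKM. In the heat shock list 11 of 23 members rose and 1 fell (11 and 2 adjusted over the list alone; higher calls, q = 2.34e-08). Hsp70Bc rose from 4.25 to 48.6 FPKM and Hsp70Bbb from 3.81 to 42.8 FPKM, while the abundant small heat shock genes Hsp23 and Hsp27 were not called, at 3110.1 and 2525 FPKM and 1502 and 1436 FPKM. The Hsp70 copies share nearly all their sequence, so the split of reads among them is uncertain, and Hsp70Aa is held by a merged entry as well as its own. Fisher's test counts these entries as separate genes, so the q of this list overstates the evidence, here and in prepupae.

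In the sarcomere list 14 of 42 tested members rose in stationary larvae and 5 fell (14 and 8 adjusted over the list alone; higher calls, q = 4.06e-08). The other 23 were not called, and the list's median log2 ratio was 0.13, at percentile 99.3 of the random lists. TpnC47D rose from 1.68 to 30.9 FPKM, Mlp60A from 8.18 to 57.9 FPKM and the myosin light chain Mlc2 from 21.0 to 93.6 FPKM. abba fell from 54.1 to 32.2 FPKM (log2 fold change -0.75 ± 0.21, q = 0.00317), and TpnC73F and Mlc-c were not called, at 386 and 424 FPKM and 468 and 329.7 FPKM. The attachment genes LanA and LanB2 and the mew entry fell, from 105 to 45.4 FPKM, from 60.9 to 40.2 FPKM and from 52.2 to 21.5 FPKM. Of 43 digestive enzymes 21 rose and 1 fell (23 and 2 adjusted over the list alone; higher calls, q = 1.1e-15), among them Amy-d from 8.15 to 103 FPKM, Amy-p from 15.4 to 132 FPKM, Mal-A1 12.4-fold and the protease Jon25Biii from 79.0 to 576 FPKM. The salivary glue genes Sgs5, Sgs1, Sgs3 and Sgs8 rose (4 of 7, 5 adjusted over the list alone; q = 0.00118), Sgs5 from 2188 to 4886 FPKM and Sgs3 from 4905 to 8545 FPKM. In the ecdysone-induced 71E cluster, which follows the glue genes in the salivary gland, 5 of 7 genes fell (6 adjusted over the list alone; q = 0.00469), among them Eig71Eb from 723 to 236 FPKM, Eig71Eg from 118 to 40.6 FPKM and Eig71Ed from 299 to 157 FPKM. These glue and cluster results missed the threshold at a q of 0.01 per gene, with 2 and 3 genes called (q = 0.136 and 0.182).

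The testis list had 35 of 56 members lower and none higher in stationary larvae (37 lower adjusted over the list alone; q = 3.58e-16), with a median log2 ratio of -2.24. The largest falls were those of w-cup from 107 to 1.21 FPKM, Acam from 72.4 to 0.798 FPKM, ran-like from 37.2 to 0.248 FPKM, I-t from 72.7 to 1.56 FPKM, dj from 107 to 3.47 FPKM, S-Lap3 from 181 to 6.58 FPKM, Tpl94D from 43.9 to 0.912 FPKM, robl62A from 105 to 4.13 FPKM, Mst33A from 91.1 to 3.83 FPKM and the sugar transporter relative sut4 from 27.8 to 0.549 FPKM. loopin-1, a leucyl aminopeptidase relative, fell from 223 to 12.5 FPKM, and CG43638, CG31802 and CG12464 fell from 81.4 to 0.278 FPKM, from 74.1 to 0.749 FPKM and from 137 to 2.42 FPKM. roX1 and roX2 were not called, at 260.0 and 350.0 FPKM and 38.3 and 28.1 FPKM. CR40469 rose from 195 to 10615 FPKM, CR41590 from 0.186 to 27.8 FPKM and CG17352 from 0.733 to 29.8 FPKM.

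Ribosomal protein genes shifted by a smaller factor in stationary larvae, with 27 of 90 higher and 2 lower (31 and 3 adjusted over the list alone; higher calls, q = 6.1e-14) and a list median of 0.35 on the log2 scale. RpL36A rose from 448 to 901 FPKM, RpL36 from 408 to 798 FPKM and RpL29 from 144 to 279 FPKM. RpL10Aa fell from 19.0 to 0.829 FPKM and was lower at every stage. Whether its fall belongs with that of the testis transcripts was not tested. The abundant members RpL41 and RpS29 were not called, at 5778 and 7122 FPKM and 3440.2 and 4181 FPKM. Detoxification genes had 13 higher and 5 lower of 49 (16 and 5 adjusted over the list alone; higher calls, q = 2.71e-06), including GstD2 from 3.83 to 24.5 FPKM, Cyp4e3 from 0.996 to 8.98 FPKM and, downward, Cyp6a17 from 14.4 to 0.163 FPKM. Of 13 haemocyte genes 3 rose and 2 fell (higher calls, q = 0.124), proPO-A1 from 1.51 to 14.0 FPKM and nimC2, downward, from 218 to 118 FPKM. The early ecdysone genes Hr4 and ImpE2 fell from 50.8 to 32.5 FPKM and from 592 to 397 FPKM, and the other 24 of 26 tested members, broad (br) at 361 and 314 FPKM among them, were not called. Adjusted over the list alone, 0 early ecdysone genes were lower, and of 16 synthesis genes Hr4 was the 1 called, with 0 adjusted over the list alone. In the fat body list the serum protein gene Lsp1beta rose from 1007 to 2224 FPKM, the lipase bmm fell from 65.3 to 44.4 FPKM and Fbp1 and Fbp2 were not called, at 9564 and 7485 FPKM and 6281 and 8733 FPKM. None of 25 neuronal and 17 insulin, TOR and juvenile hormone genes was called, with Csp at 75.8 and 79.7 FPKM and the 4E-BP gene Thor at 1386 and 1934 FPKM, and the neuronal median was 0.18, at percentile 98.6.

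In white prepupae the male germline transcripts were lower as at the earlier stages, and immune, heat shock, glue and ribosomal protein transcripts were higher. Most muscle genes were not called, as at the larval stages, and their higher calls no longer passed Fisher's test against the other genes. Sgs5 rose 5.31-fold, from 39.7 to 211 FPKM, and Dpt rose 3.00-fold, from 122 to 365 FPKM. Hsp70Aa rose 2.66-fold, from 27.3 to 72.6 FPKM, and RpL15 rose 2.04-fold, from 898 to 1828 FPKM. w-cup fell 157-fold, from 83.9 to 0.533 FPKM. The authors' deposited table called 1822 of 10780 tested genes, 1388 lower and 434 higher, with 796 of the lower and 37 of the higher changed at least 4-fold. Only 170 of the higher genes of this stage were changed at least 2-fold, and 269 were called at a q of 0.01.

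The testis list had 33 of 55 tested members lower and none higher in prepupae (40 lower adjusted over the list alone; q = 5.75e-15), with a median log2 ratio of -2.36. Acam fell from 60.5 to 0.676 FPKM, I-t from 55.0 to 0.707 FPKM, Tpl94D from 35.5 to 0.141 FPKM, S-Lap3 from 152 to 3.86 FPKM, robl62A from 86.1 to 1.78 FPKM, dj from 88.2 to 1.87 FPKM, ran-like from 28.9 to 0.0960 FPKM, S-Lap7 from 68.4 to 1.73 FPKM and Mst33A from 71.2 to 2.22 FPKM. CG12464, CG12860 and CG31909 fell from 125 to 0.732 FPKM, from 113 to 0.967 FPKM and from 112 to 2.24 FPKM. roX1 was not called, at 208 and 255 FPKM, nor was roX2, at 44 and 20.7 FPKM.

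The immune list had 19 of 49 members higher and 3 lower in prepupae (20 and 3 adjusted over the list alone; higher calls, q = 2.26e-13). Drsl6 and AttD rose from 2.16 to 29.5 FPKM and from 8.64 to 46.8 FPKM, AttA fell from 236 to 79.3 FPKM, and Drsl5 at 3229 and 3511 FPKM was not called. Heat shock genes had 11 of 23 higher and 1 lower (12 and 3 adjusted over the list alone; higher calls, q = 4.92e-09), with the small heat shock gene l(2)efl rising from 48.7 to 179.8 FPKM and Hsp70Ba from 10.2 to 25.2 FPKM. Among glue genes 6 of 7 rose (7 adjusted over the list alone; q = 3.1e-07), including Sgs3 from 49.5 to 152 FPKM, Sgs8 from 101 to 213 FPKM and Sgs1 from 3.78 to 8.78 FPKM. Eig71Ee, which both the glue list and the 71E list hold, is 1 of these and is also the rise of the 71E cluster. In the 71E cluster 4 of 9 genes fell and 1 rose (lower calls, q = 0.124), with Eig71Eg falling from 1295 to 662 FPKM and Eig71Ee rising from 41.5 to 74.6 FPKM. Ribosomal protein genes had 38 of 90 higher and 5 lower (45 and 5 adjusted over the list alone; higher calls, q = 1.59e-27), with RpL29 from 128 to 291 FPKM and RpL36A from 476 to 952 FPKM.

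Sarcomere genes were split in prepupae, with 3 of 40 higher and 4 lower (higher calls, q = 0.996). Tm2 and Prm rose from 17.9 to 33.7 FPKM and from 15.8 to 28.9 FPKM, tmod and the mew entry fell from 495 to 262 FPKM and from 44.9 to 19.0 FPKM, and abba at 59.1 and 45.5 FPKM was not called (q = 0.138). Of 38 digestive enzymes 6 rose and 3 fell (higher calls, q = 0.0247), Jon25Bi from 8.36 to 32.1 FPKM, Jon74E from 11.6 to 30.1 FPKM and, downward, etaTry from 15.1 to 3.56 FPKM. Detoxification genes had 9 higher and 7 lower of 38 (higher calls, q = 1.35e-04), with GstD5, Cyp28d1 and Cyp6a23 rising from 0.583 to 13 FPKM, from 3.12 to 21.7 FPKM and from 11.5 to 60.3 FPKM and Cyp6a17 falling from 20.9 to 0.230 FPKM. Of 15 tested fat body genes 4 fell and 2 rose (7 and 2 adjusted over the list alone; lower calls, q = 0.605), Lsp1alpha from 686 to 309 FPKM and Pepck from 460.1 to 283 FPKM downward and Fbp2 from 5586 to 9292 FPKM upward. In the ecdysone lists Eip78C rose from 36.2 to 58.0 FPKM and the ecdysone synthesis gene spok fell from 15.6 to 8.45 FPKM, and the other 25 early response and 13 synthesis genes tested were not called. None of 24 neuronal and 16 insulin, TOR and juvenile hormone genes was called in prepupae, and of 12 haemocyte genes 2 rose. Further rises were those of Cpr67Fa2 from 1.17 to 43.5 FPKM, Sytalpha from 1.63 to 33.5 FPKM, TotB from 7.75 to 78.8 FPKM, mthl6 from 0.264 to 10.3 FPKM, Cpr97Ea from 1.70 to 14.2 FPKM, CR40469 from 314 to 15655 FPKM and CG17352 from 1.21 to 38.5 FPKM. CR40596, on unplaced sequence, was listed at 0 in w1118 and at 29.2 FPKM in trans-heterozygous prepupae, and likewise at 0 and 37.4 FPKM in wandering larvae, yet fell from 29.0 to 0.0950 FPKM in stationary larvae, a stage looked up after its values were seen.

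**Figure D2:**
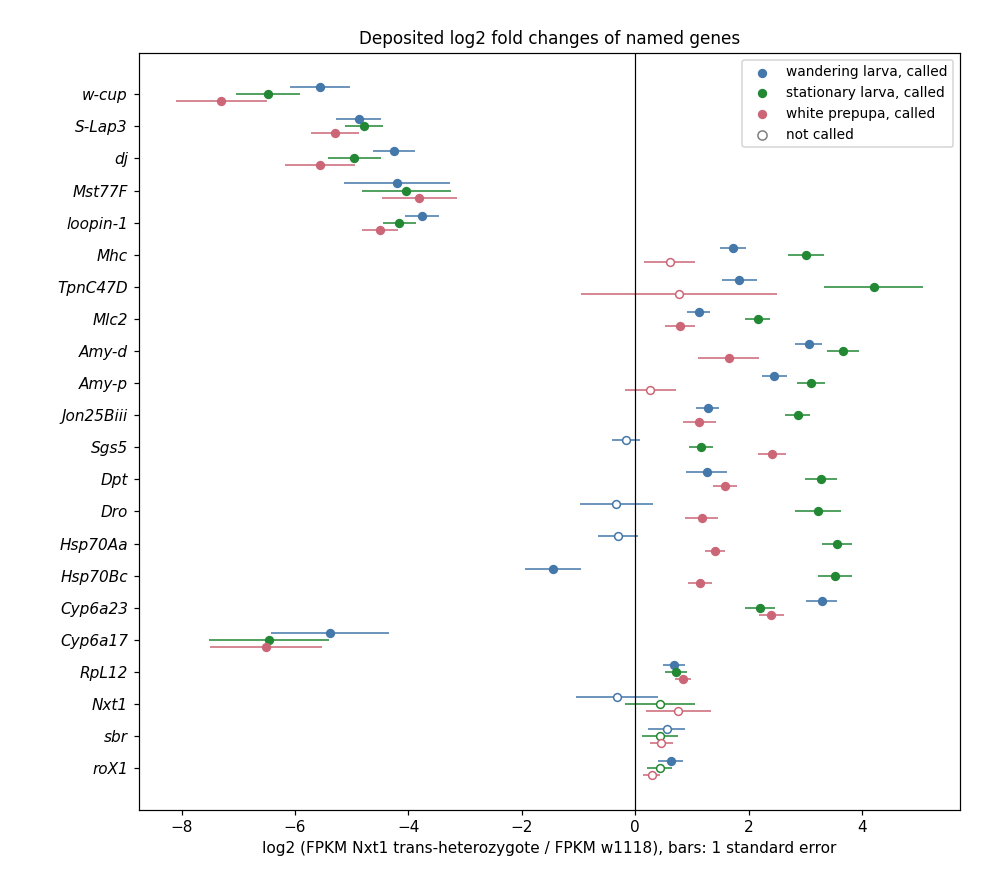
Deposited log2 fold change of Nxt1 trans-heterozygotes over w1118 (x axis) for 22 named genes (y axis) at each stage, with bars of 1 standard error; filled points passed the authors' test and open points did not. The testis genes w-cup, S-Lap3, dj, Mst77F and loopin-1 lie below -3 at all 3 stages, while Mhc goes from 3.02 in stationary larvae to 0.61 in prepupae.

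The 3 stages were then set side by side, each with its own control samples. Many genes were lower at every stage: 829 of the 1824 genes called lower at any stage, and 68 of the 813 genes called higher at any stage. The testis list contributed 31 of its 55 members tested throughout, among them S-Lap3, w-cup, Mst77F, loopin-1, dj, bol and twe. The 10 genes with the largest falls throughout were CG12860, w-cup, CG31909, CG2127, S-Lap3, CG32371, ran-like, Tpl94D, CG12464 and CG42523, of which CG2127 fell from 80.4 to 1.74 FPKM and CG32371 from 43.0 to 0.440 FPKM in prepupae. The 10 with the largest rises throughout were CG17352, CR40469, Sytalpha, CG9040, CG31810, CG8664, Cyp6a23, Cyp28d1, the merged entry CG44013,CG44014 and CG42823. CG9040 rose from 179.9 to 1434 FPKM in wandering larvae and from 2.39 to 39.1 FPKM in prepupae. Between stationary larvae and prepupae, 1120 genes were lower at both against 189.8 given by independent lists, and 212 were higher at both against 18.3. Between wandering larvae and prepupae the corresponding counts were 858 against 135 and 76 against 7.32, with 19 genes called in opposite directions. Across genes, which are not independent replicates, the log2 ratios of stationary larvae and prepupae had a Spearman correlation of 0.79.

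Some genotype effects differed between stages when the difference itself was tested. The 5 genes with the smallest p between wandering larvae and prepupae were CG13315, the P450 genes Cyp9b2 and Cyp12d1-d, CG17386 and CG31343. CG13315 rose 1.95-fold in wandering larvae and 18.2-fold in prepupae (two-sided normal test of the difference, Benjamini-Hochberg q = 1.15e-24). Cyp9b2 rose from 63.8 to 132 FPKM in wandering larvae and fell from 141 to 59.4 FPKM in prepupae (q = 9.2e-15). Between these stages 107 of 10096 genes differed, 69 of 10459 between wandering and stationary larvae, and 89 of 10338 between stationary larvae and prepupae. The effect on Mhc differed between stationary larvae and prepupae, from a log2 fold change of 3.02 to 0.61 (q = 0.00307), and the effect on TotC differed between wandering and stationary larvae, from -1.29 to 5.05 (q = 4.13e-10). At a q of 0.01 the counts of differing genes were 65, 43 and 57 in the order given above. Each stage's table was scaled on its own, and this test compares the fold changes within each stage, not levels. In data simulated with the standard errors of the wandering and prepupal tables over 10096 genes, the test recovered 24% of differences of 1 and 78% of differences of 3 on the log2 scale.

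A question raised for this export factor is whether long genes respond more than short ones. Called genes of both directions were concentrated among short loci, and dj, loopin-1 and Mst33A, each on a short locus, were among the lower ones. In stationary larvae 23.2% of genes in the shortest of 5 span bins (median 980.5 bases) and 9.93% in the longest (median 32674 bases) were lower. The shares higher were 9.30% and 1.80%. The share lower did not fall steadily with span. In the bin next to the longest and in the longest it was 4.59% and 6.61% in wandering larvae. The corresponding shares were 9.16% and 9.93% in stationary larvae and 8.02% and 9.69% in prepupae, and this upturn was not tested. The share higher fell from bin to bin at every stage. The odds ratios of longest over shortest were 0.317, 0.365 and 0.381 for lower genes in wandering larvae, stationary larvae and prepupae (two-sided Fisher's exact tests, Benjamini-Hochberg q = 1e-31, 2.27e-32 and 1.3e-28). For higher genes they were 0.219, 0.179 and 0.251 (q = 1.06e-10, 1.78e-29 and 1.2e-17). Testis list members had a median span of 2463 bases against 3959 for all genes tested in stationary larvae. The span is that of the locus in the files, which overlapping genes share and which includes introns.

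**Figure D3:**
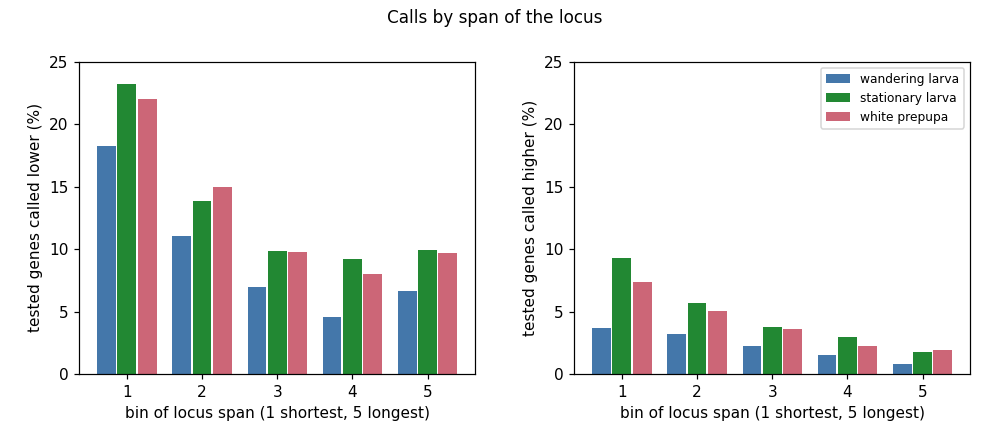
Percent of tested genes called lower (left panel) and higher (right panel) in Nxt1 trans-heterozygotes in 5 equal bins of locus span, from the shortest (1) to the longest (5), with 1 bar per stage. The shortest bin holds the highest share in both panels at every stage, 22.0% lower and 7.33% higher in prepupae.

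The authors' deposited tables also tested whether the genotypes differed in their use of isoforms, promoters and coding sequences, a set of tests separate from those of total level. Most genes called for usage were not called for their total level. The same held for all tested genes, of which 11.8%, 17.9% and 16.9% were called at the 3 stages in order. Few usage calls recurred at all 3 stages. For splicing, 5 of the 230 genes called at any stage did. For promoter usage the count was 15 of 212, and for coding-sequence usage 8 of 154. The 5 splicing genes were RpS21, a ribosomal protein gene, srpk79D, an SR protein kinase, Tsp3A, CG32581 and a merged snoRNA host entry (Uhg5). RpS21 had 198 and 239 FPKM in stationary larvae and a Jensen-Shannon distance of 0.475 between genotypes (q = 4.77e-04). The receptor gene mthl8 was called for promoter usage at each stage with a distance of 0.83 (the square root of the Jensen-Shannon divergence, whose upper limit this is), and Cul-3, a ubiquitin ligase scaffold, was called for promoter and coding-sequence usage at each. In stationary larvae Mf, dlg1, His3.3B and Pax were called for splicing with the same upper-limit distance, and in wandering larvae mRpS16, prominin-like and eIF-4E were. None of these genes was called for splicing at all 3 stages. bol, a regulator of meiotic entry, was called for coding-sequence usage at all 3 stages (q = 0.00132, 5.25e-04 and 0.0209). So was the merged entry CG15742,mew (q = 0.0260, 0.00895 and 3.97e-04). Splicing was called in 40, 101 and 129 start-site groups, promoter usage in 56, 116 and 113 genes and coding-sequence usage in 23, 82 and 83 genes at the 3 stages in order. Of the genes called for splicing, 7, 21 and 23 were also called for their total level, and of those called for promoter usage, 15, 33 and 27. Single isoforms were called 914, 1530 and 1487 times, 820, 1230 and 1115 of them lower, and start-site groups 982, 1622 and 1512 times. At a q of 0.01 the splicing counts of stationary larvae and prepupae were 64 and 80, and those at the 3 stages were 27, 68 and 64 for promoters and 14, 45 and 50 for coding sequences.

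Nxt1 and both its alleles lie on arm 2R, and called genes were not concentrated there. On 2R, which also carries S-Lap7, Amy-d and Cyp6a23, 11.8%, 18.2% and 16.6% of tested genes were called at the 3 stages, against 11.9%, 17.9% and 17.1% on the other major arms (two-sided Fisher's exact tests, unadjusted p = 0.941, 0.781 and 0.608, q = 0.950, 0.937 and 0.782 over 18 tests of arms). By direction, 2R had the largest share of higher genes among the major arms, 2.87%, 5.87% and 4.83% at the 3 stages, with 8.92%, 12.3% and 11.7% lower. Higher genes made up 1.77% to 2.80%, 3.01% to 5.12% and 2.92% to 4.26% of the other major arms. The directions were not tested apart at single stages, so a concentration of higher genes on 2R stays open. Of genes higher at all 3 stages, 2R held 0.769% of its tested genes against 0.648% elsewhere (two-sided Fisher's exact test, q = 0.975). The other arms were tested as well, without having been planned. The X chromosome, which carries roX1, sbr and CR40469, had fewer called genes than the other arms, 13.1% against 18.9% in stationary larvae (odds ratio 0.644, q = 3.3e-08). Arm 2L, which carries w-cup, Mst33A and Mhc, had more, 20.8% against 17.3% (odds ratio 1.26, q = 6.57e-04). The small chromosome 4 had the lowest share, 2.41% of 83 tested genes against 18% (odds ratio 0.113, q = 9.24e-05), and q = 0.00467 at each of the other stages. The entry that merges the eye colour gene w with CG32795 was not called for its level at any stage, with 23.1 and 22.6 FPKM in wandering larvae. The authors' test of promoter usage called this entry in prepupae (distance 0.286, q = 0.0165). The merged level does not show whether w itself differed. The body colour gene y stayed below 2 FPKM in both genotypes and was not tested by the authors in either larval stage. Its value was higher in the trans-heterozygotes each time, though near the floor. In w1118 and trans-heterozygotes it was 0.0860 and 0.174 FPKM in wandering larvae and 0.126 and 0.664 FPKM in stationary larvae. In prepupae it was 0.184 and 1.73 FPKM, and y was not called there (q = 0.684).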

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

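The tests on roX1 and roX2, on the members within each list and on the w1118 course of the immune and heat shock genes were chosen only after the result was seen, as was the look at Rbp4; the other tests here were not. The effect of genotype was not the same at every stage for some genes, by a test of the difference itself. It differed for 69 genes between wandering and stationary larvae, for 107 between wandering larvae and prepupae, and for 89 between stationary larvae and prepupae, and for 43, 65 and 57 at a q of 0.01. Among heat shock and immune genes, the log2 fold change of stationary larvae minus that of wandering larvae was 6.33 for TotC, 5.46 for Hsp70Ba, 5.35 for Hsp70Bbb, 4.97 for Hsp70Bc and 4.81 for Hsp70Bb. It was 3.87 for Hsp70Aa, 3.86 for the merged entry Hsp70Aa,Hsp70Ab, 3.55 for Dro and 2.51 for TotA. The Hsp70 copies are nearly identical, so these are not separate pieces of evidence. The same difference was 2.79 for the receptor gene mthl6, 1.59 for the protease Jon25Biii and 1.25 for the cuticle gene Lcp2.

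Between wandering larvae and prepupae, the log2 fold change of prepupae minus that of wandering larvae was 3.23 for CG13315, 2.58 for CG17386, 2.57 for Sgs5, 1.77 for CR40469, 1.64 for Sgs3, 1.5 for l(2)efl and 0.97 for RpL15. It was -2.98 for CG31343, -2.55 for Cyp12d1-d, -2.29 for Cyp9b2, -1.43 for PGRP-SC2 and -1.01 for the glycolytic enzyme Eno. From stationary larvae to prepupae, the effects on the muscle genes Mhc and Mlc2 and the gut enzyme Amy-p shrank. The difference of prepupae minus stationary larvae was -3.41 for Cpr47Eb, -2.83 for Amy-p, -2.41 for Mhc, -1.79 for IM1, -1.68 for Dpt, -1.37 for Mlc2, -1.35 for Lsp1alpha, -1.25 for AttA and -1.12 for Lsp1beta. It was 1.05 for Eip78C and 0.90 for Eig71Ea.

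The first pattern weighed was the loss of testis transcripts at all 3 stages. Fewer males in the trans-heterozygote collections would lower the male RNAs roX1 and roX2 along with them, and in wandering larvae the log2 ratio minus 2 standard errors was 0.18 for roX1 and -0.75 for roX2, against a median of -2.23 for the testis list. At the later stages it was at lowest -0.02 for roX1 but -2.03 for roX2, whose log2 ratio was -0.45 ± 0.44 in stationary larvae and -1.08 ± 0.47 in prepupae. Both bounds lie above the medians of the testis list, -2.24 and -2.36, which argues against a shortage of males as the whole cause, and a smaller shortage stays open. Small or missing testes would lower the spermatocyte regulators aly, comr, topi and tomb as well, and their median log2 ratio was at lowest -0.64 and at highest -0.03. Their FPKM lay near the floor and the median minus 2 standard errors reached -1.50, so an arrest within the germline and a smaller testis cannot be told apart by these genes. Rbp4, a spermatocyte RNA-binding protein gene, rose from 7.04 to 18 FPKM in stationary larvae and from 5.39 to 14.6 FPKM in prepupae. It was picked from several genes looked up outside the naming rule, and it shows only that not every testis transcript was lower. Strain background stays open as untested.

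The second pattern was that of stationary larvae, with digestive and glue transcripts and part of the muscle transcripts higher and the 71E cluster lower. If the trans-heterozygotes had been collected at an earlier point of development, their change should run against the w1118 change from wandering larvae to prepupae. Across the 98 members Spearman's rho was -0.63, which decides nothing, because the direction of each list was part of the pattern. With both changes centred on the median of each list, rho was -0.54 (95% bootstrap interval -0.69 to -0.36), and within single lists it was -0.72 for muscle, -0.68 for glue, -0.32 for the 71E cluster and -0.31 for digestive enzymes. Over all 11128 genes tested in stationary larvae rho was -0.27, while the effect in prepupae had -0.28 with the w1118 change between the larval stages, and the effect in wandering larvae ran the other way, at 0.20 with the w1118 change from stationary larvae to prepupae. Single lists outside the pattern ranged from -0.83 for glycolysis to 0.47 for heat shock, and most were negative. The values within the lists are those that an earlier point of development for the stationary larvae would give, but a negative rho was not particular to these lists. Genes are not independent replicates, the stages were scaled separately, and a delay of the mutants, the collection and the strain were not separated.

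The third pattern was the rise of immune and heat shock transcripts in stationary larvae. An earlier point of development would need the called members to be higher in w1118 wandering larvae than in w1118 prepupae. Their median w1118 change from wandering larvae to prepupae was instead 1.75 on the log2 scale over 35 members, with quartiles of 0.86 and 2.71, against 0.09 over all tested genes. The stages were scaled separately, but a shift common to all genes was small beside these values, which argues against that explanation for these genes. Infection, stress of handling, strain background and the Nxt1 alleles stay open, as none was tested.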

How the results depend on the processing

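None of the alternatives was chosen after its result was seen. No called result changed direction under any alternative run, though for gene calls that outcome was nearly fixed beforehand. A stricter q, a minimum fold change or a minimum FPKM cannot change a sign. Centring used median log2 ratios of 0.02, -0.02 and -0.02 at the 3 stages, against smallest called changes of 0.56, 0.51 and 0.38. At a q of 0.01 the higher genes numbered 165 in wandering larvae and 269 in prepupae, against 250 and 434 at 0.05. Counting a gene as called through any of its start-site groups gave 93 higher genes in wandering larvae and 286 in stationary larvae, and a 2-fold minimum left 170 higher genes in prepupae. The other 31 values of the counts of called genes stayed within 1.5 times the main count. The q of 0.01 also left 1 higher glycolysis gene and 2 higher cuticle genes in wandering larvae, and 2 higher glue genes and 3 lower genes of the 71E cluster in stationary larvae. These 4 results were then no longer past the Fisher threshold, while the other 44 such list values remained on their side of it. Effects that differed between stages numbered 43, 65 and 57 at a q of 0.01, for wandering against stationary larvae, wandering larvae against prepupae, and stationary larvae against prepupae. At the same q, splicing was called in 64 and 80 groups in stationary larvae and prepupae. Promoter usage was called in 27, 68 and 64 genes and coding-sequence usage in 14, 45 and 50 genes at the 3 stages in order. The stricter threshold admits fewer genes by construction, as does the 2-fold minimum. For start-site groups the cause was not tested. All 18 span values and 6 arm values kept their direction and side of the threshold under each alternative run. The 24 counts of called genes among those named stayed within 1.5 times the main count, but most of these genes had been named for large changes. The minimum of 1 FPKM removed no called isoform, start-site group or usage test, so values unchanged under it say little. Of list medians, 309 values kept their side of the 95% limits of random lists. The detoxification median in prepupae passed them under pseudocounts of 0.1 and 5, and the fat body median in prepupae no longer did under a pseudocount of 5. Total intron length from a matching annotation was not run, nor were a replicate block and leaving out each replicate, since the tables hold no values per replicate. No paired analysis was possible because the labels pair no samples and the values are pooled per genotype. With the depth unknown, a gene not called here was not shown to be unchanged.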

Other observations

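The arm tests over genes lower at all 3 stages and the look at neighbouring P450 genes were chosen only after results were seen; the list tests were not. Several groups of housekeeping and epidermal genes also moved. In wandering larvae glycolytic genes rose, 5 of 17 with none lower (9 adjusted over the list alone; one-sided Fisher's exact test, q = 2.61e-04), among them the lactate dehydrogenase ImpL3 from 37.4 to 74.4 FPKM, Gpdh from 24.3 to 44.7 FPKM, Pglym78 from 61.6 to 105 FPKM and Eno from 187 to 294 FPKM in the authors' deposited table. At a q of 0.01 per gene, 1 glycolytic and 2 cuticle genes were called higher in wandering larvae, and neither list then passed Fisher's test (q = 1 for both). Later the glycolysis list had 1 member lower and 1 higher in stationary larvae, Hex-C from 8.70 to 1.43 FPKM and the glycogen phosphorylase GlyP from 15.8 to 37.8 FPKM. Hex-C alone was lower in prepupae, from 9.81 to 2.52 FPKM. The median log2 ratio of the glycolysis list was 0.55, 0.30 and -0.21 at the 3 stages, at percentiles 100, 99.9 and 6.5 of random lists. Cuticle genes had 6 of 54 higher and 5 lower in wandering larvae (higher calls, q = 0.00956), 10 of 46 higher and 1 lower in stationary larvae (q = 3.49e-04), and 3 of 31 higher and 4 lower in prepupae (q = 0.621). Cpr11A rose at all 3 stages, from 3.32 to 20.9 FPKM, from 0.945 to 13.5 FPKM and from 0.486 to 2.59 FPKM, Cpr47Eb rose in stationary larvae from 9.05 to 71.1 FPKM, and Cpr12A fell in prepupae from 366 to 132 FPKM. The abundant larval cuticle genes Lcp4 and Lcp2 were not called in wandering larvae, at 8259 and 5626 FPKM and 3334 and 2725 FPKM.

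In genes of cell death, protein turnover and chromatin few members were called. Atg8b, an autophagy gene relative, was listed at 10.7 FPKM in w1118 and at 0 in trans-heterozygous wandering larvae, and fell from 14.6 to 0.309 FPKM in stationary larvae and from 17.7 to 0.488 FPKM in prepupae. Atg8b was thus lower at every stage, as most testis list members were, and the tissue of its fall is unknown. The death gene rpr fell from 43.7 to 25.8 FPKM and the caspase gene Nc from 75.1 to 49.7 FPKM in stationary larvae. There the stress-responsive factor Ets21C rose from 1.91 to 10.9 FPKM. In prepupae rpr fell from 137 to 96.1 FPKM and Atg8a rose from 555 to 762 FPKM. The cell death list had 1, 3 and 2 members lower and 0, 1 and 1 higher of 22 at the 3 stages in order, in no case beyond the other genes. Of 18 proteasome genes 0, 2 and 3 fell and none rose (0, 1 and 3 adjusted over the list alone), the median of the uncalled list in wandering larvae being -0.24 at percentile 0.340 of random lists, with Rpt4 going from 223 to 134 FPKM in stationary larvae and from 232 to 149 FPKM in prepupae. The merged histone entry that holds His2A:CG33820 rose from 15.4 to 53.7 FPKM in stationary larvae and from 12.9 to 38.3 FPKM in prepupae, alone among 8 tested histone entries. Among 13 respiratory chain genes ATPsyn-Cf6 alone was called, rising from 215 to 336 FPKM in wandering larvae (0 adjusted over the list alone). The median log2 ratio of that list was 0.34, 0.22 and 0.17 at the 3 stages, at percentiles 100.0, 97.6 and 94.7. Of the markers, the merged entry that holds w was called for its level at no stage, and y, tested in prepupae only, was not called there.

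Effects of opposite direction were seen at neighbouring cytochrome P450 genes on 2R. Cyp6a17 fell from 10.3 to 0.246 FPKM in wandering larvae, where Cyp6a23 rose from 7.97 to 77.7 FPKM, and both kept their direction in prepupae, from 20.9 to 0.230 FPKM and from 11.5 to 60.3 FPKM. Reads of related copies, a strain variant and a change of expression are not separated by the pooled values. Of genes lower at all 3 stages, arm 2L held 204 of 1925 tested genes (10.6% against 7.54% on the other arms; two-sided Fisher's exact test, Benjamini-Hochberg q = 1.91e-04 over 10 tests). The X chromosome held 99 of 1641 (6.03% against 8.53%; q = 0.00269).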
